A study of Mus musculus with 22 samples.

How the data were processed

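Gene expression was measured in aortas of ovariectomised female mice of 3 genotypes: wild type (WT), mice without estrogen receptor alpha (ERaKO) and mice without estrogen receptor beta (ERbKO). Each mouse carried a pellet with estradiol (E2) or with placebo for 7 to 8 days, and was 2.5 to 4.5 months old, per the labels. Each aorta gave 1 array, from 5 ug of total RNA, without pooling. The 22 arrays form 6 groups: 5 WT placebo, 5 WT E2 and 3 in each of the 4 knockout groups. The number of arrays limits the precision of every value. Arrays are named here by group and replicate number.

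The values of the deposited table are on the log2 scale and were made by the authors with GCRMA, which corrects the background by probe sequence, normalises across arrays and gives 1 value per probe set. That the scale is log2 was checked on the values: differences of group means equal the log2 fold changes that the authors deposited to within 4.98e-08. The authors also deposited a limma table with a log2 fold change and a p-value for each probe set and comparison. A limma fit of the 22 arrays over all probe sets matched the deposited p-values to within 4.94e-08, so those p-values are not adjusted for multiple tests.

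The table holds 45101 probe sets. Of these, 34958 carry 1 gene symbol in the array annotation, 932 carry several and 9211 carry none. Probe sets with several symbols or none were tested and counted, and are not reported here by name. After 64 Affymetrix control probe sets were left out, a probe set was tested when its log2 value was over 4 on at least 3 of the 22 arrays. This kept 20410 probe sets, of which 17563 carry 1 symbol and stand for 10260 named genes. Where a gene had several probe sets, the one with the highest mean over the 22 arrays was used for named genes and lists. No named gene had probe sets that changed in opposite directions, both at an unadjusted p under 0.05.

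The contrasts, gene lists, main tests and most alternatives were chosen before the data were examined, and tests of explanations, other than splits of the arrays, after. A group-means model of the 6 groups was fitted with lmFit and eBayes of limma 3.58.1 in R 4.3.3, and 10 contrasts were taken. They are the E2 effect in each genotype, the 3 differences between those effects (interaction terms), and each knockout against WT with placebo and with E2. P-values were adjusted by Benjamini-Hochberg over the tested probe sets of a contrast, and an adjusted p under 0.05 is a call. All limma tests are two-sided. The words rose and fell are used for calls; for a difference between genotypes the words higher and lower are used. Errors beside a log2 change are the standard errors (SE) of the limma fit, and errors beside a group mean are standard deviations (SD) between arrays.

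Named genes follow a fixed rule. In each contrast they are the 15 largest rises and the 15 largest falls among called genes whose arrays separate the groups, with no such condition for interaction terms. Where fewer than 5 genes qualified, the 5 with the smallest unadjusted p are given as values. Some of the 4 members of each list with the smallest unadjusted p are named too, and Esr1, Esr2, Pgr, Greb1, Sod3, Nos3, Ucp1, Adipoq, Acta1 and Myh11 always. Greb1 and Esr2 did not pass the filter.

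Of 27 gene lists, 26 had at least 5 tested genes and were tested with camera of limma at a preset correlation between genes of 0.01, adjusted over the lists of a contrast. The erythroid list had fewer and is given as values. Counts of called members were made over all tested probe sets and, for each list, adjusted over the list alone. The list of electron transport chain genes follows a group that the study itself reported from these samples (O'Lone et al.), so its direction is not independent evidence here. With the correlation estimated from the data, 0 of the 106 camera calls among 260 pairs of list and contrast were kept. The median, mean and camera direction of a list differed in sign in 51 of the 260 pairs, 1 of them a camera call. The mean of each list per array was also compared between E2 and placebo by two-sided exact permutation tests.

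The slope of each knockout's E2 changes on those of WT was computed over the genes called in WT. The slopes of the knockouts were compared by redrawing the knockout labels within treatment 100 times, the real grouping included. The labels give no pairs. Replicate numbers were checked by correlating, across tested probe sets, the deviations of an E2 array from its group mean with those of the placebo array of the same number. These r were 0.25 to 0.66 in the 11 pairs within a genotype, and in 10 the array of the same number gave the highest r, so a fit with the replicate block is an alternative. Probe sets are not independent replicates in these r.

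Alternatives for each result were other low-value filters, other normalisations between arrays, other thresholds, other variance models, array weights and 1 probe set per gene. Further ones were only the groups of a contrast in the fit, the replicate block, marker scores of fat and striated muscle as covariates, the authors' own table and leaving out each array in turn. Added after seeing the data were the replicate block together with the brown adipocyte score, leaving out WT placebo arrays 1 and 4 together, regroupings of the knockouts that keep the pairs and, for the mean of the electron transport chain list, differences within pairs of equal replicate number.

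Fits were tested on simulated data with the real probe set spread and group sizes, 0.5 of the variance given to pairs and 200 changed probe sets per E2 effect. Of changed probe sets in WT, ERaKO and ERbKO, the model recovered 62, 29 and 36% at a log2 change of 1. At 2 it recovered 88, 85 and 78%. The block fit recovered 79, 63 and 45% at 1 and 95, 95 and 92% at 2. False calls were 0 in 5 of the 6 E2 contrasts and 1 in the other, and 7 to 17 with the block. Camera called a shift of 0.5 in 1 list (adjusted p = 3.5e-15) and 0 of 25 other lists. No gene correlation was set, so the preset 0.01 was not tested. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.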

Results

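Expression was measured on Affymetrix whole-genome mouse arrays in aortas of 22 ovariectomised female mice, 1 array per mouse. There were 5 WT mice with placebo, 5 WT mice with E2, and 3 mice in each of the ERaKO placebo, ERaKO E2, ERbKO placebo and ERbKO E2 groups. The median log2 signal of an array was between 3.26 and 3.50, and between 18452 and 19329 probe sets per array were over a log2 value of 4. Arrays of the same group correlated across probe sets with r of 0.90 to 0.98, with a median of 0.96 over 32 pairs of arrays.

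The comparison of E2 with placebo in WT asked which aortic transcripts respond to estrogen. In WT aortas with E2 (n = 5) against placebo (n = 5), Mmd2, a gene of the progestin and adipoQ receptor family, rose by 4.44 ± 0.25 (adjusted p = 2.0e-09) on the log2 scale. Ano4, a member of the anoctamin family of membrane proteins, rose by 4.29 ± 0.19 (adjusted p = 7.3e-11). The log2 signal of Mmd2 was 3.90 ± 0.51 (SD, n = 5) with placebo and 8.34 ± 0.21 (SD, n = 5) with E2. Both genes are at background with placebo, so their rises are lower bounds and differences between low values hold noise. Vwf, which encodes the von Willebrand factor made by endothelial cells, rose by 1.93 ± 0.17 (adjusted p = 3.6e-06). Among called genes whose arrays separate the groups, the largest falls were those of Sost, an inhibitor of Wnt signalling, with -1.71 ± 0.35 (adjusted p = 0.033), and Rgs5, a regulator of G-protein signalling in vascular mural cells, with -1.41 ± 0.22 (adjusted p = 0.0024), while the Wnt inhibitor gene Wif1, with overlapping arrays, had -2.08. In all, limma called 79 probe sets, of which 71 rose and 8 fell, for 61 named genes (1626 probe sets at an unadjusted p under 0.05).

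Among enzymes, 2 members of the aldo-keto reductase family rose, Akr1c14 by 3.03 ± 0.36 (adjusted p = 1.5e-04) and Akr1cl by 1.91 ± 0.25 (adjusted p = 4.4e-04). Galnt15, a glycosyltransferase, rose by 2.26 ± 0.23 (adjusted p = 1.8e-05), and Heph, the ferroxidase hephaestin, by 2.04 ± 0.20 (adjusted p = 1.3e-05). Of secreted proteins, the glycoprotein hormone stanniocalcin 1 (Stc1) rose by 2.12 ± 0.24 (adjusted p = 9.2e-05), the protease inhibitor Serpina3n by 2.11 ± 0.31 (adjusted p = 0.0017) and the matrix protein gene Spon1 by 1.76 ± 0.27 (adjusted p = 0.0018). Rises were also called for Trim10, by 2.19 ± 0.39 (adjusted p = 0.0096), and the matrix proteoglycan gene Bcan, by 1.91 ± 0.36 (adjusted p = 0.016). Aff3 rose by 1.91 ± 0.25 (adjusted p = 4.4e-04) and the prostaglandin transporter gene Slco2a1 by 1.89 ± 0.29 (adjusted p = 0.0018). Rsad2, an interferon-induced antiviral protein, rose by 1.88 ± 0.39 (adjusted p = 0.033). The growth factor receptor gene Fgfr2 fell, with a log2 change of -0.98 ± 0.19 (adjusted p = 0.024), and so did the ATP-gated channel gene P2rx5, with -0.93 ± 0.20 (adjusted p = 0.048). The call of Bcan was lost without WT E2 2 (adjusted p = 0.059), and that of Fgfr2 without WT placebo 1, 2 or 3 or WT E2 1 or 3 (highest adjusted p = 0.082). Of the 22 removals of a single array, 9 ended the call of Rsad2 (highest adjusted p = 0.10), 7 that of Sost (0.10) and 19 that of P2rx5 (0.16), and without WT E2 2 the count was 52. With the replicate number as a block the count was 347, of which 199 rose and 148 fell.

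Of 71 electron transport chain genes, 0 rose and 0 fell by limma (0 higher and 28 lower at an unadjusted p under 0.05), and 0 and 1 adjusted over the list alone. Electron transport chain calls with the replicate block were 0 and 11, and 0 and 60 adjusted over the list alone. Their median was -0.49, and camera called the list lower (adjusted p = 1.9e-24, and 0.38 with an estimated correlation). This list follows a group that the study chose on these samples, so its count and direction are not independent evidence. The log2 changes of Ndufb2, a subunit of complex I, and of the ATP synthase subunits Atp5d, Atp5j2 and Atp5e were -0.71 ± 0.17, -0.59 ± 0.17, -0.56 ± 0.18 and -0.60 ± 0.19. Their adjusted p were 0.078, 0.27, 0.35 and 0.35, and those of Ndufb2 and Atp5j2 were 0.0049 and 0.037 with the replicate block. The mean log2 signal of the list was 11.27 ± 0.25 (SD, n = 5) with E2 and 11.74 ± 0.43 (SD, n = 5) with placebo (two-sided exact permutation p = 0.0635, 0.284 after Benjamini-Hochberg adjustment), and it was lower with E2 in 5 of 5 pairs of equal replicate number (paired exact permutation p = 0.0625, the smallest possible). The means of 4 other lists had a smaller p in WT. None of 26 passed adjustment there (smallest adjusted p = 0.21, from the lowest possible p, 0.0079). None could in the knockouts (lowest possible p, 0.1). Of 34 TCA cycle and fatty acid oxidation genes, 0 rose and 0 fell by limma (0 higher and 10 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. TCA cycle and fatty acid oxidation calls with the replicate block were 0 and 5, and 0 and 29 adjusted over the list alone. The list median was -0.66, and camera called the list lower (adjusted p = 1.6e-13, and 0.38 with an estimated correlation). The markers of fat cells had lower values in the same arrays. Of 16 brown adipocyte genes, 0 rose and 0 fell by limma (0 higher and 6 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. Brown adipocyte calls with the replicate block were 0 and 3, and 0 and 11 adjusted over the list alone. The brown adipocyte median was -1.0, and camera called the list lower (adjusted p = 4.8e-07, and 0.38 with an estimated correlation). Of 18 white adipocyte genes, 0 rose and 0 fell by limma (0 higher and 3 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. White adipocyte calls with the replicate block were 0 and 1, and 0 and 11 adjusted over the list alone. The white adipocyte median was -0.66, and camera called the list lower (adjusted p = 8.4e-06, and 0.46 with an estimated correlation). With each adipocyte score as covariate, never a list's own, 5 of 11 list calls in WT were kept. They were extracellular matrix, endothelial, brown adipocyte (white score), heat shock and complement. Of brown adipocyte markers, Cox7a1 had -1.16 ± 0.47 (adjusted p = 0.53, and 0.0069 with the replicate block). Cidea had -1.11 ± 0.39 (adjusted p = 0.41, and 0.028 with the replicate block) and Ucp1 -0.68 ± 0.39 (adjusted p = 0.69). Of white adipocyte markers, Cidec had a value of -1.16 ± 0.50 (adjusted p = 0.58, and 0.04995 with the replicate block) and Adipoq, the adipokine adiponectin, -0.60 ± 0.36 (adjusted p = 0.71). Camera did not call the list of striated muscle markers (median -0.43, adjusted p = 0.058, and 0.026, lower, with the replicate block).

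Of 24 endothelial marker genes, 1 rose and 0 fell by limma (5 higher and 2 lower at an unadjusted p under 0.05), and 5 and 1 adjusted over the list alone. Endothelial marker calls with the replicate block were 2 and 0, and 6 and 1 adjusted over the list alone. The endothelial marker median was 0.22, and camera called the list higher (adjusted p = 0.0019, and 0.38 with an estimated correlation). Besides Vwf, the endothelial transcription factor Sox18 had a value of 1.01 ± 0.32 (adjusted p = 0.33) and the tight junction gene Cldn5 0.83 ± 0.24 (adjusted p = 0.23, and 0.025 with the replicate block). Of 14 complement, chemokine and adhesion genes, 1 rose and 0 fell by limma (5 higher and 0 lower at an unadjusted p under 0.05), and 2 and 0 adjusted over the list alone. Complement, chemokine and adhesion calls with the replicate block were 1 and 0, and 5 and 0 adjusted over the list alone. The list median was 0.48, and camera called the list higher (adjusted p = 1.9e-05, and 0.38 with an estimated correlation). Lbp, the lipopolysaccharide binding protein, rose by 1.70 ± 0.35 (adjusted p = 0.035). Of 21 estrogen-responsive genes, 1 rose and 0 fell by limma (2 higher and 4 lower at an unadjusted p under 0.05), and 1 and 2 adjusted over the list alone. Estrogen-responsive calls with the replicate block were 2 and 1, and 3 and 5 adjusted over the list alone. The estrogen-responsive median was -0.12, and camera did not call the list (adjusted p = 0.17). Pgr, the progesterone receptor, rose by 1.58 ± 0.32 (adjusted p = 0.030). Of 37 antioxidant enzyme genes, 1 rose and 0 fell by limma (3 higher and 1 lower at an unadjusted p under 0.05), and 1 and 0 adjusted over the list alone. Antioxidant enzyme calls with the replicate block were 1 and 0, and 3 and 1 adjusted over the list alone. The antioxidant enzyme median was -0.016 (mean 0.0059, camera direction up), and camera did not call the list (adjusted p = 0.94). The member that rose was Gclc, the catalytic subunit of the enzyme that starts glutathione synthesis, by 1.64 ± 0.21 (adjusted p = 3.4e-04), and Sod3, the extracellular superoxide dismutase, had a value of -0.17 ± 0.19 (adjusted p = 0.86). Of 29 vasoactive signalling genes, 0 rose and 1 fell by limma (3 higher and 3 lower at an unadjusted p under 0.05), and 2 and 2 adjusted over the list alone. Vasoactive signalling calls with the replicate block were 0 and 2, and 4 and 2 adjusted over the list alone. The vasoactive signalling median was -0.0031 (mean 0.017, camera direction up), and camera did not call the list (adjusted p = 0.94). The member that fell was Rgs5, and the endothelial nitric oxide synthase gene Nos3 had a value of 0.10 ± 0.23 (adjusted p = 0.94). Of 46 extracellular matrix genes, 0 rose and 0 fell by limma (5 higher and 10 lower at an unadjusted p under 0.05), and 4 and 8 adjusted over the list alone. Extracellular matrix calls with the replicate block were 1 and 2, and 5 and 11 adjusted over the list alone. The list median was -0.18, and camera called the list lower (adjusted p = 0.0034, and 0.66 with an estimated correlation). The collagen gene Col1a1 had a value of -1.25 ± 0.28 (adjusted p = 0.058, and 0.026 with the replicate block). Of 29 smooth muscle genes, 0 rose and 0 fell by limma (4 higher and 0 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. The smooth muscle median was 0.26, and camera called the list higher (adjusted p = 0.021, and 0.77 with an estimated correlation). Myh11, the smooth muscle myosin heavy chain, had a value of 0.26 ± 0.20 (adjusted p = 0.78). Single-array removals ended the call of Pgr in 8 cases (highest adjusted p = 0.095) and that of Lbp in 10 (0.13). The smooth muscle call was lost without WT placebo 2 or 4 or WT E2 2 or 3 (highest adjusted p = 0.94). The extracellular matrix call was lost without WT placebo 3 (highest adjusted p = 0.074).

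Camera also called further lists in WT. Adventitial fibroblast genes were called higher (median 0.17, adjusted p = 0.019, and 0.66 with an estimated correlation). That call was lost without WT placebo 4 or 5 or WT E2 1 or 3 (highest adjusted p = 0.26). Heat shock genes were called lower (median -0.18, adjusted p = 9.5e-05, and 0.38 with an estimated correlation). Ribosomal protein genes were called higher (median 0.22, adjusted p = 2.3e-05, and 0.47 with an estimated correlation). No call was made for NADPH oxidase genes (median 0.20, adjusted p = 0.087), macrophage genes (median 0.16, adjusted p = 0.41), lymphocyte genes (median -0.38, adjusted p = 0.16) and Schwann cell and neuronal genes (median -0.025, mean -0.092, camera direction up, adjusted p = 0.94). The same held for mesothelial genes (median -0.17, adjusted p = 0.49), cholesterol synthesis genes (median -0.080, adjusted p = 0.15), fatty acid synthesis genes (median -0.25, adjusted p = 0.10, and 0.017 with the replicate block) and cell cycle genes (median -0.024, adjusted p = 0.16). Nor were calls made for circadian clock genes (median 0.11, adjusted p = 0.94), immediate early genes (median 0.21, adjusted p = 0.17) and interferon-stimulated genes (median 0.086, adjusted p = 0.052, and 0.030 with the replicate block). The erythroid list was too short to be tested, and its member Slc4a1, the anion exchanger of red cells, had a value of 2.50 ± 0.60 (adjusted p = 0.091, and 0.023 with the replicate block).

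**Figure D1:**
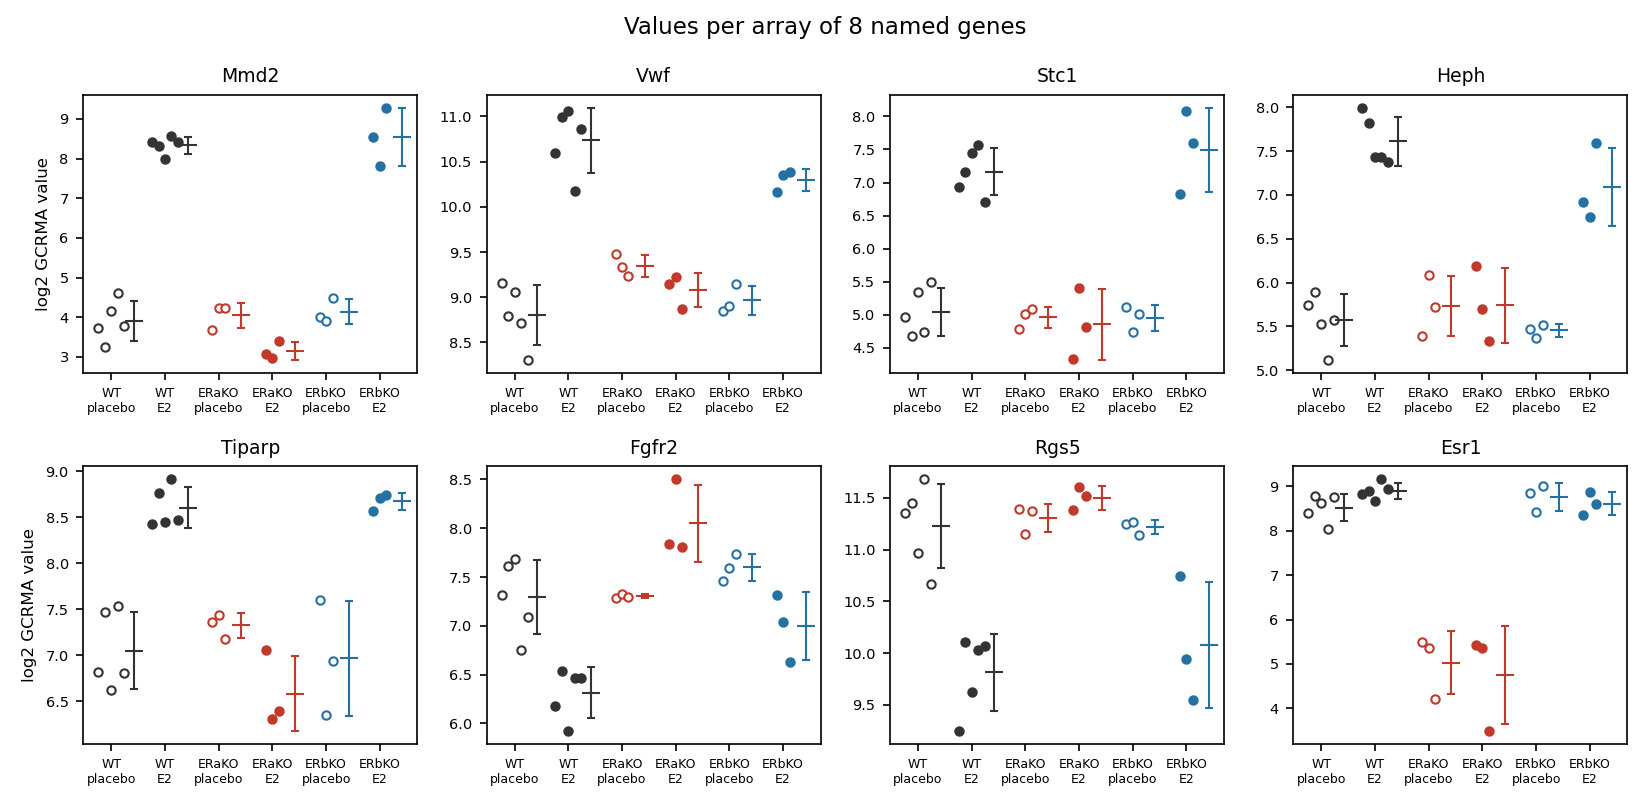
Log2 expression of 8 genes on each of the 22 arrays, by genotype and treatment (filled points, E2; open points, placebo; bars, mean ± SD of the group). Mmd2 was at 3.90 with placebo and 8.34 with E2 in WT, at 4.05 and 3.15 in ERaKO, and at 4.14 and 8.55 in ERbKO.

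The comparison of E2 with placebo in ERaKO asked which responses are present without estrogen receptor alpha. In ERaKO aortas with E2 (n = 3) against placebo (n = 3), the single called probe set was that of Brd8, a bromodomain protein of a histone acetyltransferase complex, which rose by 1.23 ± 0.18 (adjusted p = 0.042). Its log2 signal was 5.96 ± 0.25 (SD, n = 3) with placebo and 7.20 ± 0.069 (SD, n = 3) with E2, and its 5 tested probe sets had changes from -0.59 to 1.23, so a rise of the gene as a whole is not shown. The genes with the next smallest p were Coq8b (-1.07 ± 0.21), Egr2 (1.29 ± 0.26), Lrrn1 (0.73 ± 0.16) and Pcsk5 (1.71 ± 0.38), with adjusted p of 0.49, 0.49, 0.51 and 0.51. With the replicate block the adjusted p of Coq8b, Egr2 and Lrrn1 were 0.022, 0.034 and 0.042. Mmd2 had a value of -0.90 in ERaKO, from group means of 4.05 ± 0.31 and 3.15 ± 0.23, and Pgr had a value of 0.60 ± 0.41 (adjusted p = 0.86). Of 71 electron transport chain genes, 0 rose and 0 fell by limma (0 higher and 52 lower at an unadjusted p under 0.05), and 0 and 40 adjusted over the list alone. Electron transport chain calls with the replicate block were 0 and 33, and 0 and 67 adjusted over the list alone. Their median was -0.74, and camera called the list lower (adjusted p = 1.1e-35, and 0.31 with an estimated correlation). The study chose this list on these samples. Of 34 TCA cycle and fatty acid oxidation genes, 0 rose and 0 fell by limma (0 higher and 24 lower at an unadjusted p under 0.05), and 0 and 8 adjusted over the list alone. TCA cycle and fatty acid oxidation calls with the replicate block were 0 and 18, and 0 and 31 adjusted over the list alone. The list median was -1.02, and camera called the list lower (adjusted p = 5.4e-19, and 0.31 with an estimated correlation). Fat cell markers had lower values in the same arrays. Of 18 white adipocyte genes, 0 rose and 0 fell by limma (0 higher and 11 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. White adipocyte calls with the replicate block were 0 and 6, and 0 and 17 adjusted over the list alone. The white adipocyte median was -1.27, and camera called the list lower (adjusted p = 6.6e-11, and 0.31 with an estimated correlation). Of 16 brown adipocyte genes, 0 rose and 0 fell by limma (0 higher and 8 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. Brown adipocyte calls with the replicate block were 0 and 3, and 0 and 12 adjusted over the list alone. The brown adipocyte median was -1.33, and camera called the list lower (adjusted p = 4.7e-07, and 0.31 with an estimated correlation). Adipoq had a value of -1.17 ± 0.47 (adjusted p = 0.66, and 0.036 with the replicate block) and Ucp1 -1.14 ± 0.50 (adjusted p = 0.69). Camera did not call the striated muscle list (median -0.62, adjusted p = 0.27).

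Of 24 immediate early genes, 0 rose and 0 fell by limma (4 higher and 0 lower at an unadjusted p under 0.05), and 1 and 0 adjusted over the list alone. Immediate early calls with the replicate block were 1 and 0, and 1 and 0 adjusted over the list alone. The immediate early median was 0.83, and camera called the list higher (adjusted p = 1.1e-09, and 0.31 with an estimated correlation). Egr2, a transcription factor induced early after many stimuli, was the member called over the list alone. Antioxidant enzyme genes were called lower (median -0.17, adjusted p = 0.037, and 0.33 with an estimated correlation, and adjusted p = 0.066 with the replicate block). The antioxidant enzyme call was lost without ERaKO placebo 1 or 3 or ERaKO E2 1 or 2 (highest adjusted p = 0.20). Vasoactive signalling genes were called higher (median 0.30, adjusted p = 0.0048, and 0.33 with an estimated correlation). Smooth muscle genes were called higher (median 0.33, adjusted p = 4.1e-05, and 0.50 with an estimated correlation). Extracellular matrix genes were called higher (median 0.22, adjusted p = 2.1e-04, and 0.52 with an estimated correlation). The extracellular matrix call was lost without ERaKO E2 2 (highest adjusted p = 0.087). Endothelial marker genes were called lower (median -0.37, adjusted p = 3.6e-04, and 0.31 with an estimated correlation). Cholesterol synthesis genes were called lower (median -0.54, adjusted p = 0.0011, and 0.50 with an estimated correlation). The cholesterol synthesis call was lost without ERaKO E2 2 (highest adjusted p = 0.051). Fatty acid synthesis genes were called lower (median -1.06, adjusted p = 5.5e-06, and 0.39 with an estimated correlation). Heat shock genes were called higher (median 0.22, adjusted p = 2.5e-05, and 0.31 with an estimated correlation). Tested with each adipocyte score as covariate, the calls of the electron transport, immediate early and heat shock lists were kept, 3 of 13, and the fatty acid synthesis median turned to 0.16 (white) and 0.045 (brown). The Nos3 value was -0.64 ± 0.30 (adjusted p = 0.71). The immediate early call was lost without ERaKO E2 1 (highest adjusted p = 0.20). The other lists, striated muscle aside, were not called, with adjusted p from 0.17 for the complement list to 0.93 for the estrogen-responsive list. In all, limma called 1 probe set, which rose (1385 at an unadjusted p under 0.05), and 340 with the replicate block, of which 19 rose and 321 fell. The Brd8 call was lost in 17 of the 22 removals of a single array (highest adjusted p = 0.58) and kept without WT placebo 4, WT E2 5, ERaKO placebo 1, ERbKO placebo 1 or ERbKO placebo 2. Without ERaKO placebo 1 the count was 5.

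The comparison of E2 with placebo in ERbKO asked which responses are present without estrogen receptor beta. In ERbKO aortas with E2 (n = 3) against placebo (n = 3), Mmd2 rose by 4.41 ± 0.33 (adjusted p = 2.2e-07), Ano4 by 3.41 ± 0.25 (adjusted p = 2.2e-07) and Stc1 by 2.54 ± 0.32 (adjusted p = 4.1e-04). The log2 signal of Mmd2 was 8.55 ± 0.74 with E2 and 4.14 ± 0.31 with placebo, near background, so its rise is a lower bound. The zinc finger gene Bnc2 rose by 2.16 ± 0.38 (adjusted p = 0.022, and 0.060 with the replicate block), Galnt15 by 2.03 ± 0.30 (adjusted p = 0.0046) and Tiparp, a poly(ADP-ribose) polymerase family member, by 1.71 ± 0.29 (adjusted p = 0.017). Heph rose by 1.63 ± 0.26 (adjusted p = 0.011), Hrct1 by 1.47 ± 0.18 (adjusted p = 3.7e-04) and the lipoprotein receptor gene Vldlr by 1.38 ± 0.24 (adjusted p = 0.021). Vwf rose by 1.33 ± 0.23 (adjusted p = 0.017) and the growth hormone receptor gene Ghr by 1.25 ± 0.22 (adjusted p = 0.022). Casq1, the calsequestrin of skeletal muscle, fell (-1.81 ± 0.34, adjusted p = 0.044). Pgr had a value of 1.34 ± 0.41 (adjusted p = 0.80) and Rgs5 -1.14 ± 0.29 (adjusted p = 0.38). The adipocyte scores kept 8 of 12 list calls in ERbKO, and ended those of the electron transport, TCA cycle, macrophage and fatty acid synthesis lists. In all, limma called 20 probe sets, of which 19 rose and 1 fell, for 14 named genes (489 at an unadjusted p under 0.05), and 35 with the replicate block. Of the 19 probe sets that rose, 17 were among the 71 that rose in WT, against 0.0661 expected by chance (Fisher's exact test, p = 3.4e-41), and the 1 that fell was not among the 8 that fell in WT. The count was 11 without ERbKO placebo 2, 7 without ERbKO placebo 3, 12 without ERbKO E2 1, and 11 without ERbKO E2 2 or ERbKO E2 3. Removals of a single array ended the call of Galnt15 (without ERbKO placebo 3, adjusted p = 0.060) and Heph (without ERbKO placebo 2 or 3 or ERbKO E2 3, highest 0.10). They also ended those of Vwf (each of the 6 ERbKO arrays, highest 0.12) and Casq1 (16 of 22, highest 0.34). They ended the calls of Tiparp (5 of 22, highest adjusted p = 0.15), Bnc2 (4 of 22, 0.15), Vldlr (5 of 22, 0.15) and Ghr (5 of 22, 0.21) when ERbKO arrays were left out, and never those of Mmd2, Ano4, Stc1 and Hrct1.

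Of 71 electron transport chain genes, 0 rose and 0 fell by limma (0 higher and 0 lower at an unadjusted p under 0.05), and 0 and 0 adjusted over the list alone. Their median was -0.19, and camera called the list lower (adjusted p = 0.0020, and 0.81 with an estimated correlation). The electron transport chain call was lost without ERbKO placebo 1 or ERbKO E2 2 (highest adjusted p = 0.73). White adipocyte genes were not called (median -0.27, adjusted p = 0.35). Brown adipocyte genes were not called (median -0.29, adjusted p = 0.45). Of 46 extracellular matrix genes, 0 rose and 0 fell by limma (3 higher and 7 lower at an unadjusted p under 0.05), and 1 and 4 adjusted over the list alone. Extracellular matrix calls with the replicate block were 0 and 0, and 2 and 4 adjusted over the list alone. The extracellular matrix median was -0.33, and camera called the list lower (adjusted p = 2.2e-04, and 0.76 with an estimated correlation). Of 24 endothelial marker genes, 1 rose and 0 fell by limma (1 higher and 2 lower at an unadjusted p under 0.05), and 1 and 1 adjusted over the list alone. The endothelial marker median was -0.047 (mean -0.058, camera direction up), and camera did not call the list (adjusted p = 0.68). Aplnr had a value of -2.47 ± 0.66 (adjusted p = 0.46). Of 20 striated muscle genes, 0 rose and 1 fell by limma (0 higher and 1 lower at an unadjusted p under 0.05), and 0 and 1 adjusted over the list alone. The striated muscle median was -0.45, and camera did not call the list (adjusted p = 0.13). TCA cycle and fatty acid oxidation genes were called lower (median -0.25, adjusted p = 0.0056, and 0.81 with an estimated correlation). That call was lost without ERbKO placebo 1 or ERbKO E2 2 (highest adjusted p = 0.76). Adventitial fibroblast genes were called higher (median 0.12, adjusted p = 0.0019, and 0.76 with an estimated correlation). That call was lost without ERbKO placebo 3 or ERbKO E2 3 (highest adjusted p = 0.29). Macrophage genes were called higher (median 0.30, adjusted p = 0.034, and 0.81 with an estimated correlation). The macrophage call was lost without WT placebo 1, ERbKO placebo 2 or 3 or ERbKO E2 2 or 3 (highest adjusted p = 0.98). Lymphocyte genes were called lower (median -0.60, adjusted p = 0.0044, and 0.76 with an estimated correlation). The lymphocyte call was lost without ERbKO placebo 3 or ERbKO E2 1 (highest adjusted p = 0.23). Cholesterol synthesis genes were called lower (median -0.38, adjusted p = 0.0020, and 0.76 with an estimated correlation). The cholesterol synthesis call was lost without ERbKO placebo 1 (highest adjusted p = 0.11). Fatty acid synthesis genes were called lower (median -0.58, adjusted p = 0.0056, and 0.81 with an estimated correlation). The fatty acid synthesis call was lost without ERbKO placebo 1 or ERbKO E2 2 or 3 (highest adjusted p = 0.48). Cell cycle genes were called lower (median -0.14, adjusted p = 0.048, and 0.81 with an estimated correlation, and adjusted p = 0.14 with the replicate block). The cell cycle call was lost in 14 of 22 removals (highest adjusted p = 0.94). Immediate early genes were called higher (median 0.49, adjusted p = 1.2e-04, and 0.76 with an estimated correlation). Heat shock genes were called higher (median 0.11, adjusted p = 8.0e-04, and 0.76 with an estimated correlation). Ribosomal protein genes were called higher (median 0.12, adjusted p = 2.2e-04, and 0.76 with an estimated correlation). The ribosomal protein call was lost without ERbKO placebo 1 (highest adjusted p = 0.081).

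Whether the response to E2 depends on estrogen receptor alpha was tested by the difference of the E2 effects of ERaKO and WT. The E2 effect was lower in ERaKO (n = 3 and 3) than in WT (n = 5 and 5) for Mmd2, with a difference of -5.33 ± 0.42 (adjusted p = 4.7e-07), and Ano4, with -4.25 ± 0.32 (adjusted p = 3.1e-07). The signals of both in ERaKO are at background, so these differences include variation there. Lower effects were also called for Vwf, with -2.20 ± 0.29 (adjusted p = 0.0013), and Heph, with -2.03 ± 0.33 (adjusted p = 0.015). So were those for Tiparp, with -2.30 ± 0.37 (adjusted p = 0.012), and Stc1, with -2.22 ± 0.40 (adjusted p = 0.039, and 0.095 with the replicate block). The differences were lower as well for the transcription factor gene Lmo2, with -1.82 ± 0.33 (adjusted p = 0.039), the interleukin 4 receptor gene Il4ra, with -1.65 ± 0.29 (adjusted p = 0.039), and Ghr, with -1.51 ± 0.28 (adjusted p = 0.042). Fgfr2, which fell in WT, had a positive difference of 1.72 ± 0.31 (adjusted p = 0.039, and 0.11 with the replicate block). Differences of -0.98 ± 0.52 (adjusted p = 1) for Pgr and 1.60 ± 0.36 (adjusted p = 0.20) for Rgs5 were not called. In all, limma called 14 probe sets, 1 higher and 13 lower in ERaKO (635 at an unadjusted p under 0.05), and 29 with the replicate block. Of 24 endothelial marker genes, 0 had a higher and 1 a lower effect by limma (0 higher and 10 lower at an unadjusted p under 0.05), and 0 and 2 adjusted over the list alone. Endothelial marker calls with the replicate block were 0 and 1, and 0 and 6 adjusted over the list alone. The endothelial marker median was -0.65, and camera called the list lower (adjusted p = 1.3e-09, and 0.086 with an estimated correlation). The heat shock list was called higher (median 0.43, adjusted p = 2.6e-13, and 0.078 with an estimated correlation). Electron transport chain genes were called lower (median -0.30, adjusted p = 1.6e-04, and 0.76 with an estimated correlation). Brown adipocyte genes were not called (median -0.37, adjusted p = 0.54). White adipocyte genes were called lower (median -0.55, adjusted p = 0.012, and 0.76 with an estimated correlation). The white adipocyte call was lost without WT placebo 1, 3 or 5, ERaKO placebo 1 or ERaKO E2 2 (highest adjusted p = 0.64). The adipocyte scores kept 8 of 14 list calls, not that of the electron transport list. The electron transport chain call was lost without WT placebo 3, ERaKO placebo 1 or ERaKO E2 2 (highest adjusted p = 0.72). The count was 9 without WT placebo 2, WT E2 2, ERaKO E2 2 or ERbKO placebo 3, and 7 without ERaKO placebo 2 or ERaKO E2 3. Removals ended the call of Tiparp without ERaKO placebo 2 or ERaKO E2 2 or 3 (highest adjusted p = 0.071) and of Heph without ERaKO placebo 2 or 3 or ERaKO E2 2 or 3 (0.092). They ended it in 17 of 22 cases for Fgfr2 (highest adjusted p = 0.17), 13 for Stc1 (0.16), 15 for Lmo2 (0.21), 13 for Il4ra (0.15) and 18 for Ghr (0.21), and in none for Mmd2, Ano4 and Vwf.

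The same question for estrogen receptor beta was asked by the difference between ERbKO and WT. For this difference limma called 0 probe sets (261 at an unadjusted p under 0.05). The genes with the smallest p were Slc12a2 (1.06 ± 0.31), Dnajb1 (1.49 ± 0.46), Myrip (-1.18 ± 0.37), Sdc1 (-1.08 ± 0.34) and Tubgcp2 (-0.63 ± 0.20), each with an adjusted p of 1. Electron transport chain genes were called higher (median 0.26, adjusted p = 1.0e-12, and 0.81 with an estimated correlation). TCA cycle and fatty acid oxidation genes were called higher (median 0.34, adjusted p = 2.5e-06, and 0.91 with an estimated correlation). That call was lost without ERbKO placebo 2 or ERbKO E2 1 (highest adjusted p = 0.12). Heat shock genes were called higher (median 0.27, adjusted p = 7.5e-12, and 0.13 with an estimated correlation). Brown adipocyte genes were called higher (median 0.57, adjusted p = 2.4e-05, and 0.66 with an estimated correlation). The brown adipocyte call was lost without ERbKO placebo 2 (highest adjusted p = 0.0502). White adipocyte genes were called higher (median 0.29, adjusted p = 0.0012, and 0.91 with an estimated correlation). The white adipocyte call was lost without WT placebo 4, ERbKO placebo 2 or ERbKO E2 1 (highest adjusted p = 0.40). Endothelial marker genes were called lower (median -0.42, adjusted p = 0.0032, and 0.66 with an estimated correlation). That call was lost without WT placebo 5 or ERbKO E2 1 (highest adjusted p = 0.082). The adipocyte scores ended the calls of the electron transport, TCA cycle and white adipocyte lists. Between the knockouts (ERbKO minus ERaKO, n = 3 in each group), the E2 effect was higher in ERbKO for Mmd2, by 5.31 ± 0.47 (adjusted p = 5.2e-06), and Ano4, by 3.37 ± 0.35 (adjusted p = 6.9e-05), sizes that include variation of ERaKO at background. It was also higher for Stc1, by 2.64 ± 0.45 (adjusted p = 0.028, and 0.088 with the replicate block), Tiparp, by 2.45 ± 0.41 (adjusted p = 0.028), and Hrct1, by 1.57 ± 0.25 (adjusted p = 0.025, and 0.071 with the replicate block). Here limma called 9 probe sets, all higher in ERbKO (569 at an unadjusted p under 0.05). Electron transport chain genes were called higher (median 0.59, adjusted p = 5.4e-19, and 0.50 with an estimated correlation). White adipocyte genes were called higher (median 0.93, adjusted p = 1.4e-06, and 0.50 with an estimated correlation). Brown adipocyte genes were called higher (median 0.93, adjusted p = 1.6e-04, and 0.50 with an estimated correlation). The brown adipocyte call was lost without ERaKO E2 2 (highest adjusted p = 0.18). Extracellular matrix genes were called lower (median -0.53, adjusted p = 1.3e-08, and 0.50 with an estimated correlation). Only the extracellular matrix call, of 10, was kept with the adipocyte scores. The count was 3 without ERbKO placebo 3, 4 without ERaKO placebo 1, ERaKO E2 3 or ERbKO placebo 2, and 5 without ERaKO placebo 2 or 3, ERaKO E2 1 or 2, or any of ERbKO E2 1, 2 and 3. Removals ended the call of Stc1 in 9 of 22 cases (highest adjusted p = 0.11), of Tiparp in 10 (0.11) and of Hrct1 in 8 (0.10). Of the 61 named genes called in WT, 53 were called by their probe set with the highest mean, of which 53 had the WT sign in ERbKO and 28 in ERaKO, and the median change in the WT direction was 1.24 in ERbKO and 0.0096 in ERaKO. The slope of the knockout change on the WT change across these genes was 0.80 for ERbKO and -0.051 for ERaKO, and the difference of 0.85 was the largest of 100 regroupings of the knockout arrays (two-sided permutation p = 0.01, highest other 0.83). These regroupings break the pairs of equal replicate number; of the 10 that keep them the real one was the largest (highest other 0.39), which allows no p under 0.1. Over the 187 genes called with the replicate block the difference was 0.49 (two-sided permutation p = 0.15), so the call was lost. Genes are not independent replicates in these slopes.

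**Figure D2:**
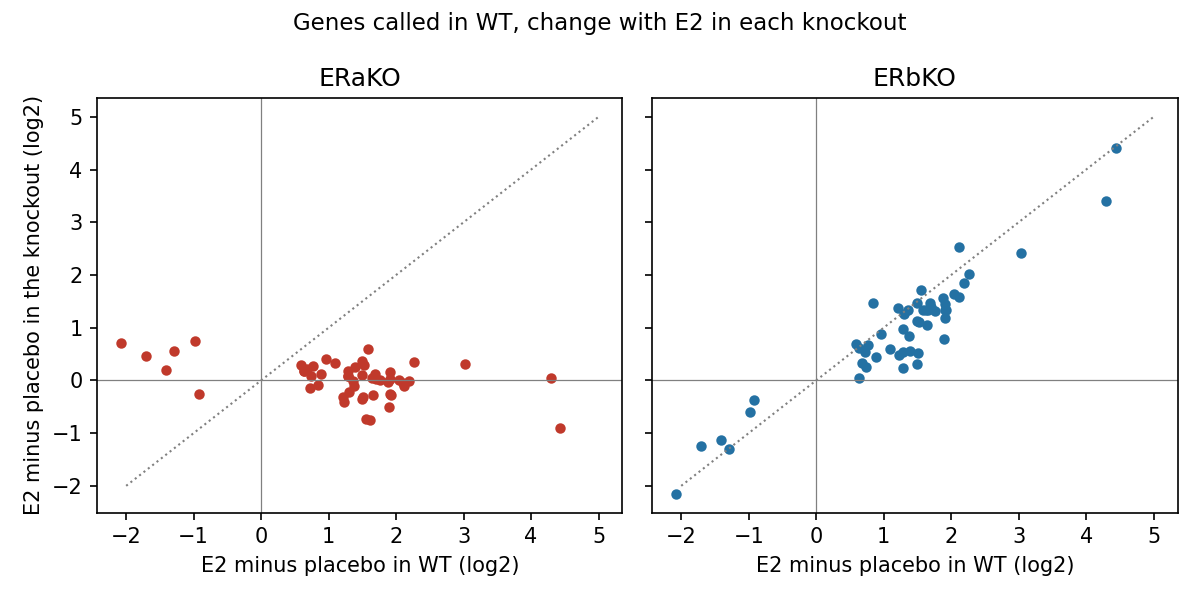
Log2 change with E2 in each knockout against the log2 change in WT for the 53 genes whose probe set with the highest mean was called in WT; each point is a gene, and the dotted line marks equal changes. The slopes were 0.80 in ERbKO and -0.051 in ERaKO.

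The comparisons of each knockout with WT asked what the missing receptor changes at a given treatment, and they check the genotypes. With placebo, Esr1, the gene of estrogen receptor alpha, was lower in ERaKO (n = 3) than in WT (n = 5), with a difference of -3.49 ± 0.36 (adjusted p = 1.4e-04). A second Esr1 probe set had -1.76 ± 0.34 (adjusted p = 0.48) and was not called. The log2 signal of Esr1 was 8.52 ± 0.31 (SD, n = 5) in WT placebo, 5.03 ± 0.71 (SD, n = 3) in ERaKO placebo and 8.76 ± 0.31 (SD, n = 3) in ERbKO placebo. It was the single probe set that limma called (739 at an unadjusted p under 0.05), and the median of all changes was 0.12, against which the list medians of this comparison are to be read. Genes with the next smallest p were Anxa8 (1.04 ± 0.22), Adat2 (1.64 ± 0.35), Pcsk5 (-1.60 ± 0.34) and Zfp317 (-1.74 ± 0.38), none called. The count was 4 without WT placebo 4, 2 without WT E2 4 and 17 without ERaKO placebo 1. Macrophage genes were called lower (median -0.46, adjusted p = 7.0e-08, and 0.48 with an estimated correlation). The macrophage call was lost without ERaKO placebo 2 (highest adjusted p = 0.054). Heat shock genes were called lower (median -0.24, adjusted p = 2.0e-08, and 0.29 with an estimated correlation). Electron transport chain genes were called higher (median 0.29, adjusted p = 0.0033, and 0.93 with an estimated correlation). The electron transport chain call was lost without WT placebo 3 or 5 or ERaKO placebo 1 (highest adjusted p = 0.90). Striated muscle genes were called lower (median -0.40, adjusted p = 0.012, and 0.85 with an estimated correlation). The striated muscle call was lost without WT placebo 1, WT E2 5 or ERaKO placebo 2 or 3 (highest adjusted p = 0.52). Extracellular matrix genes were called lower (median 0.024, mean -0.013, camera direction down, adjusted p = 0.0033, and 0.85 with an estimated correlation). The extracellular matrix call was lost without WT placebo 3 or ERaKO placebo 1 (highest adjusted p = 0.25). Adipocyte scores ended it and the electron transport call. Between ERbKO and WT with placebo, limma called 1 probe set, which was lower in ERbKO and carries no single symbol (620 at an unadjusted p under 0.05). The named genes with the smallest p included Sntg2 (-1.85 ± 0.38) and Twist2 (-1.10 ± 0.27). That count was 0 in 13 removals of a single array, 2 without WT placebo 2, WT E2 1 or 4 or ERbKO placebo 1, and 3 without ERbKO E2 2. The 13 arrays were WT placebo 1, 3 and 5, WT E2 2, 3 and 5, ERaKO placebo 3, ERaKO E2 2 and 3, ERbKO placebo 2 and 3, and ERbKO E2 1 and 3. Striated muscle genes were called lower (median -1.34, adjusted p = 9.4e-05, and 0.76 with an estimated correlation). The striated muscle call was lost without WT placebo 1 (highest adjusted p = 0.15). Electron transport chain genes were called lower (median -0.33, adjusted p = 8.6e-12, and 0.76 with an estimated correlation). Brown adipocyte genes were called lower (median -0.80, adjusted p = 2.1e-04, and 0.76 with an estimated correlation). The brown adipocyte call was lost without WT placebo 4 or ERbKO placebo 2 (highest adjusted p = 0.16). Smooth muscle genes were called higher (median 0.40, adjusted p = 1.6e-07, and 0.76 with an estimated correlation). The adipocyte scores ended the call of the electron transport list. No probe set of Esr2 passed the filter, and its group means were between 2.36 and 2.57 on the log2 scale, at background, so it checks nothing about the ERbKO genotype.

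With E2, ERaKO (n = 3) was lower than WT (n = 5) in Mmd2, with -5.19 ± 0.29 (adjusted p = 1.6e-09), Ano4, with -4.28 ± 0.22 (adjusted p = 5.6e-10), and Esr1, with -4.14 ± 0.36 (adjusted p = 2.0e-06). The sizes for Mmd2 and Ano4 include variation at background, where ERaKO is. Lower values were also called for Akr1c14 (-2.69 ± 0.42, adjusted p = 0.0031) and Gpx3, an extracellular glutathione peroxidase (-2.56 ± 0.42, adjusted p = 0.0060). Further lower genes were Stc1 (-2.31), Tiparp (-2.02), Akr1cl (-2.01), Heph (-1.87), Serpina3n (-1.85), Il4ra (-1.75), Vwf (-1.66), Vldlr (-1.58), Gclc (-1.56), Angptl1 (-1.68) and Adh1 (-1.63), the last with the highest adjusted p of these (0.049). Higher in ERaKO were the Wnt inhibitors Wif1, by 2.43 ± 0.49 (adjusted p = 0.044), and Sost, by 2.09 ± 0.40 (adjusted p = 0.028). Higher values were also called for Fgfr2, by 1.74 ± 0.22 (adjusted p = 3.1e-04), and Rgs5, by 1.68 ± 0.26 (adjusted p = 0.0025). So were Id3 (1.61 ± 0.33), Mfap4 (1.5 ± 0.31), Rmnd1 (1.09 ± 0.17) and Lrrn1 (0.71 ± 0.14), with adjusted p of 0.047, 0.044, 0.0026 and 0.044. In all, limma called 49 probe sets, 12 higher and 37 lower (1593 at an unadjusted p under 0.05), but at an unadjusted p under 0.01 the higher ones were more (287 against 173), as with the block and the brown score (137 against 129). Of 24 endothelial marker genes, 0 were called higher and 1 lower by limma (0 higher and 5 lower at an unadjusted p under 0.05), and 0 and 5 adjusted over the list alone. The endothelial marker median was -0.31, and camera called the list lower (adjusted p = 8.0e-08, and 0.28 with an estimated correlation). Macrophage genes were called lower (median -0.62, adjusted p = 9.5e-07, and 0.51 with an estimated correlation). Of 46 extracellular matrix genes, 1 were called higher and 0 lower by limma (12 higher and 0 lower at an unadjusted p under 0.05), and 7 and 0 adjusted over the list alone. The extracellular matrix median was 0.42, and camera called the list higher (adjusted p = 4.1e-05, and 0.57 with an estimated correlation). The macrophage call was lost without ERaKO E2 3 (adjusted p = 0.084). The electron transport list was not called (median -0.017, adjusted p = 0.080). The count was 76 without WT placebo 4, 31 without WT E2 1, 91 without ERaKO E2 1, 28 without ERaKO E2 2 and 30 without ERaKO E2 3. The call was lost for Akr1c14 without ERaKO E2 3 (adjusted p = 0.055) and Gpx3 without ERaKO E2 2 (0.066). It was lost for Sost without WT E2 1 or any ERaKO E2 array (highest 0.15) and Angptl1 without WT E2 1 or 4 or ERaKO E2 2 or 3 (0.14). Of 22 removals, 7 ended the call of Serpina3n (highest adjusted p = 0.24), 16 that of Id3 (0.23), 17 each those of Wif1 (0.25), Mfap4 (0.32) and Adh1 (0.32), and 19 that of Lrrn1 (0.31). Between ERbKO and WT with E2, limma called 1 probe set, lower in ERbKO and without a single symbol (1172 at an unadjusted p under 0.05). Among the genes with the smallest p were Sntg2, with -2.33 ± 0.38 (adjusted p = 0.073), Ap4s1 (-0.73 ± 0.15) and Tcp11l2 (-0.87 ± 0.19). That count was 2 without WT placebo 5, 3 without ERbKO placebo 3, 8 without ERbKO E2 1, and 0 without WT E2 1, 4 or 5, ERaKO placebo 3, or ERbKO E2 2 or 3. Striated muscle genes were called lower (median -1.23, adjusted p = 0.0019, and 0.94 with an estimated correlation). Heat shock genes were called higher (median 0.20, adjusted p = 5.0e-07, and 0.39 with an estimated correlation). Endothelial marker genes were called lower (median -0.47, adjusted p = 1.5e-04, and 0.42 with an estimated correlation).

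**Figure D3:**
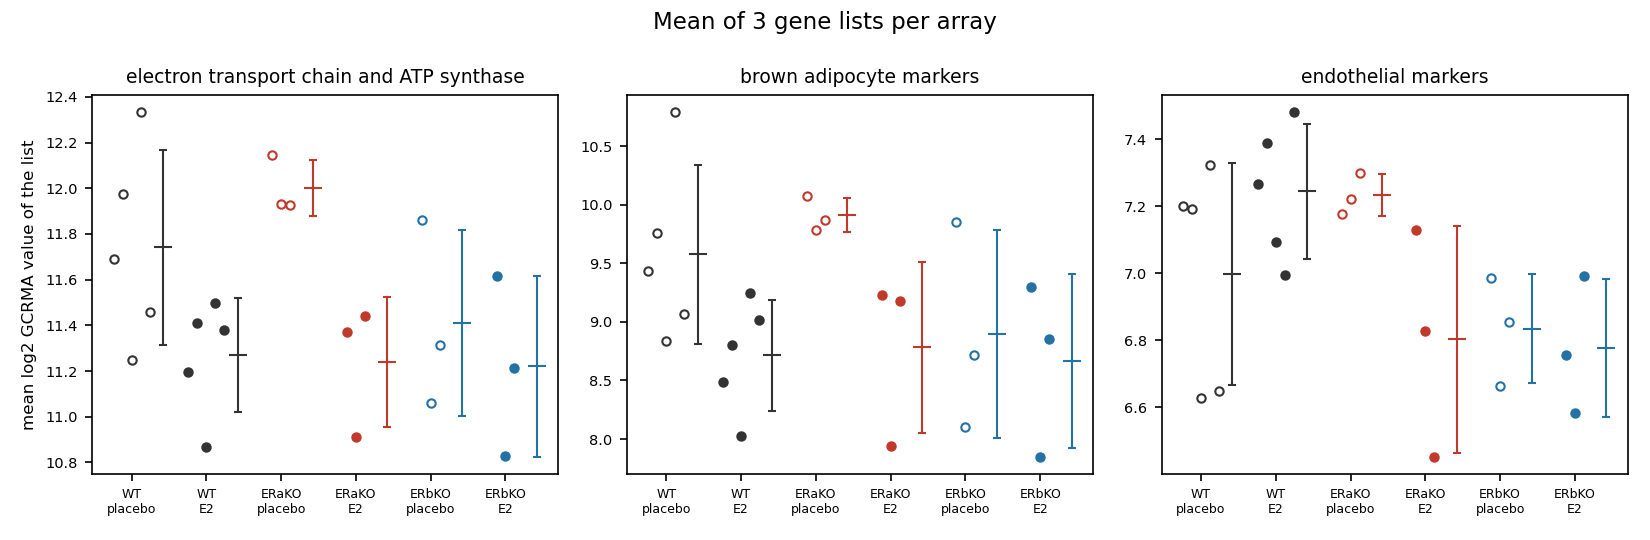
Mean log2 expression per array of the electron transport chain genes, the brown adipocyte markers and the endothelial markers, by genotype and treatment (filled points, E2; open points, placebo; bars, mean ± SD). The mean of the electron transport chain genes was 11.74 with placebo and 11.27 with E2 in WT.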

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

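All tests of explanations in this part were chosen after the results were seen, except the counts over other splits of the arrays. In WT placebo 4 the list mean was the lowest of its group for NADPH oxidase and related genes (7.22), vasoactive signalling genes (7.32) and extracellular matrix genes (9.05), and so was the log2 signal of Myh11 (12.19). In the same array Nos3 was the highest of the group (7.63). In WT placebo 1 the highest values of the group were those of the striated muscle markers (10.05), lymphocyte markers (6.05), cell cycle genes (6.81) and Acta1, the skeletal muscle actin (10.09). Each of these values lay far from the other 4 arrays of the group by Dixon's test. They are 9 of 106 groups tested, and chance gives such a value in about 1 in 20 groups, or 5.3 groups here. WT placebo 4 also had the highest means of its group for the white adipocyte (11.27), brown adipocyte (10.79) and electron transport lists (12.33), by less than that test needs. Without it the E2 change of these means in WT was -0.41, -0.56 and -0.32, against -0.68, -0.86 and -0.47 with it.

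The E2 effect differed between ERaKO and WT, by the interaction term of limma, for Mmd2 (-5.33), Ano4 (-4.25), Tiparp (-2.30), Stc1 (-2.22), Vwf (-2.20), Heph (-2.03), Lmo2 (-1.82), Il4ra (-1.65), Ghr (-1.51) and Fgfr2 (1.72). Between ERbKO and ERaKO it differed for Mmd2 (5.31), Ano4 (3.37), Stc1 (2.64), Tiparp (2.45) and Hrct1 (1.57).

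The absence of these responses in ERaKO is a pattern that 2 technical explanations were set against. With both adipocyte scores in the fit, 8 of the 14 called probe sets were still called, and the median of the 13 lower differences went from -2.20 (median SE 0.33) to -2.11 (0.35), which argues against less fat cell RNA in the E2 arrays as the whole cause. Less endothelial RNA in the ERaKO E2 arrays is left open. Endothelial markers had a median difference of -0.65 (quartile farther from 0, -1.01), but called differences (quartile nearer to 0, -1.84) were selected as large. A need for estrogen receptor alpha, the factor of the design, may account for the pattern and stays a hypothesis. A part due to changes in cell composition remains open.

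The lower electron transport chain transcripts with E2 are a pattern seen beside lower fat cell markers. Within groups the list mean followed the brown (Pearson r = 0.97, Spearman rho = 0.93, r = 0.96 without the 2 farthest arrays) and white adipocyte scores (0.95, 0.95 and 0.95) over 22 arrays. Each permutation p was 1e-05, the smallest possible, and 1e-05 adjusted for 2 relations. The scores hold 16 and 18 genes and share 0 with the list, but the brown score holds Cox7a1, a subunit of complex IV. With the white score alone the E2 change of the list mean in WT was -0.15 (95% interval -0.30 to 0.0028), against -0.47 without it. With both it was -0.065 (-0.20 to 0.068), and -0.098 (-0.28 to 0.081) within pairs, as less fat cell RNA in the E2 arrays could give. In ERaKO it was -0.17 (-0.34 to -0.0017) over all arrays and -0.25 (-0.53 to 0.031) within pairs, so fat cell RNA as the whole cause is left open there. A response that needs estrogen receptor beta cannot be told apart from none, because the difference between ERbKO and WT was 0.28 with an interval of -0.46 to 1.02 over all arrays and -0.12 to 0.68 within pairs, which holds both 0 and the whole fall in WT. The list mean was lower with E2 in 5 of 5 WT, 3 of 3 ERaKO and 3 of 3 ERbKO pairs, and an effect of E2 on the fat cells themselves was not tested.

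Genes next to the targeted genes are a pattern that DNA from the strain in which the gene was targeted might give. Among 27 neighbours of Esr1 (assembly GRCm38.p6), 1 differed between ERaKO and WT in the same direction at an unadjusted p under 0.05 in both treatments, Mthfd1l (0.98 with placebo and 1.15 with E2), and 9.69% of 9680 windows held as many, while on the whole chromosome 6 of 513 genes did so (Fisher's exact test, p = 0.021), which leaves the explanation open. Among 40 neighbours of Esr2, 2 did so between ERbKO and WT, Snapc1 (-0.45 and -0.50) and Syne2 (-0.46 and -0.86), and 1.46% of 9401 windows held as many (5 of 361 genes on the chromosome, Fisher's exact test, p = 0.022), which is consistent with DNA around the targeted gene from the strain in which it was targeted. No biological explanation was tested, and an effect of the missing receptor on these genes remains open.

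Other splits of the same arrays were counted for each number of called probe sets. For the E2 effect in WT, 2 of 100 splits, the real one included, gave as many calls (real 79, highest other 394). This share is under 0.05, but ignores the replicate pairs. Of the 16 splits that part as many pairs the real one was highest (highest other 0), but 16 allow no share under 0.05. For ERaKO minus WT, 4 of 100 splits gave as many (real 14, highest other 719). Of 56 that keep the pairs, 1 did (highest other 1). These shares, unadjusted over 10 contrasts, do not exclude chance. In ERaKO (4 of 10 splits, real 1, highest other 23) and ERbKO (1 of 10, real 20, highest other 4) the splits are too few for a share under 0.05, as are the 4 splits of each that part the pairs (highest other 0 in both). For ERbKO minus WT the real count was 0, so that 100 of 100 splits gave as many whatever the values (highest other 2988), which tests nothing. Chance is not excluded for ERbKO minus ERaKO (5 of 100, real 9, highest other 20; the 10 splits that keep the pairs, highest other 0, are too few), ERaKO against WT with placebo (12 of 56, real 1, highest other 263) and with E2 (4 of 56, real 49, highest other 475), and ERbKO against WT with placebo (7 of 56, real 1, highest other 864) and with E2 (11 of 56, real 1, highest other 198). Splits with several times the real count point to a structure of the samples: the split with 394 calls in WT set WT placebo 1 and 3 and WT E2 1, 2 and 3 against the rest, which keeps both arrays of replicates 1 and 3 on one side and both of replicates 4 and 5 on the other.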

How the results depend on the processing

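The block together with the brown adipocyte score, leaving out WT placebo 1 and 4 together, the differences within pairs used above and the slopes of regroupings that keep the pairs were chosen after seeing the data; the other alternatives were not. Of 75 named gene calls, the filter at log2 over 6 kept 65 of 65 that it could test, a second quantile normalisation kept 72, centred array medians 69, the trended and robust prior 74, array weights 66, the replicate block 70, the brown, white and striated scores 70, 72 and 65, and values under 4 set to 4 kept 66. Leaving out the filter kept 53, only the groups of a contrast 28, leaving out WT placebo 1 and 4 together 60, and the block with the brown score 52; 0 of the 75 reversed in any of these settings. The replicate numbers did not pair across genotypes (r -0.34 to 0.39 over 12 pairs, 5 over 0.1), so for comparisons between genotypes the block is only a check. The following counts of called probe sets moved by more than 1.5 times, where ERaKO placebo stands for the comparison of ERaKO with WT on placebo, and so on. At an adjusted p under 0.10 the count was 126 for E2 in WT, 22 for ERaKO minus WT, 2 for ERbKO placebo, 75 for ERaKO E2 and 2 for ERbKO E2. At an unadjusted p under 0.01 the count was 500 for E2 in WT, 304 for E2 in ERaKO, 174 for E2 in ERbKO, 168 for ERaKO minus WT, 24 for ERbKO minus WT, 97 for ERbKO minus ERaKO, 114 for ERaKO placebo, 83 for ERbKO placebo, 460 for ERaKO E2 and 236 for ERbKO E2. With only the groups of a contrast in the fit the count was 27 for E2 in WT, 0 for E2 in ERaKO, 2 for E2 in ERbKO, 4 for ERbKO minus ERaKO, 0 for ERaKO placebo, 0 for ERbKO placebo, 12 for ERaKO E2 and 0 for ERbKO E2. With array weights the count was 165 for E2 in WT, 240 for E2 in ERbKO, 17 for ERaKO placebo, 5 for ERbKO placebo and 239 for ERbKO E2. With the replicate block the count was 347 for E2 in WT, 340 for E2 in ERaKO, 35 for E2 in ERbKO, 29 for ERaKO minus WT, 2 for ERaKO placebo, 0 for ERbKO placebo, 155 for ERaKO E2 and 0 for ERbKO E2. Without WT placebo 1 and 4 together the count was 41 for E2 in WT, 0 for ERbKO placebo and 0 for ERbKO E2. With the block and the brown adipocyte score together the count was 17 for E2 in WT, 0 for E2 in ERaKO, 4 for ERbKO minus ERaKO, 2 for ERaKO placebo, 266 for ERaKO E2 and 0 for ERbKO E2. After a second quantile normalisation the count was 0 for E2 in ERaKO. With array medians centred the count was 0 for E2 in ERaKO. With a trended, robust variance prior the count was 0 for E2 in ERaKO and 0 for ERbKO placebo. With the brown adipocyte score in the fit the count was 0 for E2 in ERaKO, 24 for ERaKO minus WT, 2 for ERbKO placebo and 83 for ERaKO E2. With the white adipocyte score in the fit the count was 0 for E2 in ERaKO, 25 for ERaKO minus WT and 2 for ERbKO placebo. With the striated muscle score in the fit the count was 0 for E2 in ERaKO and 2 for ERbKO placebo. With 1 probe set per gene the count was 13 for E2 in ERbKO, 5 for ERbKO minus ERaKO, 0 for ERbKO placebo and 0 for ERbKO E2. Without a filter on low values the count was 9 for ERaKO minus WT, 5 for ERbKO minus ERaKO, 0 for ERbKO placebo and 0 for ERbKO E2. With the filter at log2 over 6 the count was 2 for ERbKO placebo and 2 for ERbKO E2. With values under 4 set to 4 the count was 0 for ERbKO placebo and 2 for ERbKO E2. With the authors' p-values adjusted over the tested probe sets the count was 0 for ERbKO placebo and 0 for ERbKO E2. Only the groups of a contrast give fewer arrays to estimate the spread, and a filter or a threshold changes the number of probe sets tested or called by its construction; for the other settings the cause was not tested. The slope difference of 0.85 was 0.83 with array medians centred, 0.49 with the replicate block and 0.88 with the block and brown score, and 5, 15 and 6 of 100 regroupings were as large; the cause was not tested. The lower Esr1 value with placebo was -3.49 with only the groups of the contrast, with an adjusted p of 0.052. Of 106 camera calls, 0 were kept with an estimated correlation, which widens the test by the correlation of the genes in a list.

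Leaving out each array in turn gave counts of 52 to 79 for E2 in WT, 0 to 5 for E2 in ERaKO, 7 to 27 for E2 in ERbKO, 7 to 21 for ERaKO minus WT, 0 to 0 for ERbKO minus WT, 3 to 11 for ERbKO minus ERaKO, 1 to 17 for ERaKO placebo, 0 to 3 for ERbKO placebo, 28 to 91 for ERaKO E2 and 0 to 8 for ERbKO E2. The slope difference ranged from 0.76 to 0.91, the Esr1 difference with placebo from -3.73 to -3.09 and the number of camera calls from 95 to 113. The number of arrays and, for genes near a log2 value of 4, the signal over background limit all of these results.

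Gene lists whose camera direction reversed, with at least 1 of the calls made, are given with their median under the setting; the cause was not tested. Direction here is that of camera, by which 79 of 8780 comparisons reversed; by the sign of the median it would be 125, and 5 were called both times in opposite directions. A second quantile normalisation, array medians centred and the replicate block reversed 0. With the brown adipocyte score in the fit these were TCA cycle and fatty acid oxidation -0.14 (ERbKO minus WT), 0.033 (E2 in WT), 0.14 (ERbKO placebo), then cholesterol synthesis -0.10 (E2 in ERaKO), 0.16 (ERbKO placebo), then ribosomal protein -0.15 (E2 in ERaKO), -0.077 (ERbKO placebo), then electron transport chain -0.035 (ERbKO minus WT), 0.018 (ERbKO placebo), then fatty acid synthesis -0.45 (ERbKO minus ERaKO), 0.045 (E2 in ERaKO), 0.46 (E2 in WT), 0.57 (ERbKO placebo), then smooth muscle 0.00083 (E2 in WT), then white adipocyte -0.19 (ERbKO minus WT), 0.18 (E2 in WT), 0.34 (ERbKO placebo). Without WT placebo 1 and 4 together these were striated muscle -1.22 (ERaKO minus WT), -0.76 (ERbKO minus WT), 0.60 (ERaKO placebo). Without a filter on low values these were extracellular matrix 0.11 (ERbKO placebo). With the block and the brown adipocyte score together these were TCA cycle and fatty acid oxidation -0.10 (ERbKO minus WT), 0.069 (ERaKO placebo), 0.14 (ERbKO placebo), then cholesterol synthesis -0.18 (E2 in ERaKO), 0.21 (ERbKO placebo), then ribosomal protein 0.081 (ERbKO minus WT), -0.26 (E2 in ERaKO), -0.055 (E2 in WT), then electron transport chain 0.030 (ERbKO placebo), then endothelial marker 0.0058 (ERbKO minus ERaKO), -0.093 (E2 in ERaKO), then extracellular matrix 0.14 (ERbKO minus WT), -0.28 (E2 in ERaKO), then fatty acid synthesis 0.19 (E2 in WT), 0.74 (ERbKO placebo), then smooth muscle 0.047 (ERbKO minus ERaKO), -0.22 (E2 in ERaKO), -0.17 (E2 in WT), then white adipocyte -0.12 (ERbKO minus WT), 0.051 (E2 in WT), 0.43 (ERbKO placebo). With the filter at log2 over 6 these were cell cycle -0.023 (E2 in ERbKO). With the white adipocyte score in the fit these were TCA cycle and fatty acid oxidation 0.091 (ERaKO minus WT), -0.12 (ERbKO minus ERaKO), 0.18 (ERaKO E2), then brown adipocyte 0.33 (ERaKO minus WT), -0.085 (ERbKO minus ERaKO), -0.0047 (E2 in ERaKO), then cholesterol synthesis -0.029 (E2 in ERaKO), then ribosomal protein -0.16 (E2 in ERaKO), then electron transport chain 0.0089 (ERaKO minus WT), 0.089 (ERaKO placebo), then fatty acid synthesis -0.55 (ERbKO minus ERaKO), 0.16 (E2 in ERaKO), 0.33 (E2 in WT), -0.031 (ERaKO placebo). Leaving out 1 array reversed further lists, given with the range of the median over the 22 removals and the arrays whose removal reversed it. For ERbKO minus ERaKO they were immediate early -0.82 to 0.15 (ERaKO E2 1). For ERaKO E2 they were immediate early 0.091 to 1.24 (ERaKO E2 1), TCA cycle and fatty acid oxidation -0.18 to 0.36 (ERaKO E2 2), brown adipocyte -0.30 to 0.46 (ERaKO E2 2), electron transport chain -0.13 to 0.12 (ERaKO E2 2) and white adipocyte -0.41 to 0.17 (ERaKO E2 2). For ERaKO minus WT they were TCA cycle and fatty acid oxidation -0.60 to -0.044 (ERaKO E2 2), electron transport chain -0.44 to -0.14 (ERaKO E2 2), white adipocyte -0.82 to -0.21 (ERaKO E2 2), macrophage -0.60 to 0.45 (ERaKO E2 3) and striated muscle -1.01 to 0.79 (WT placebo 1). For E2 in ERbKO they were cell cycle -0.19 to -0.047 (ERbKO E2 1), TCA cycle and fatty acid oxidation -0.58 to 0.062 (ERbKO E2 2 or ERbKO placebo 1), electron transport chain -0.37 to 0.040 (ERbKO E2 2 or ERbKO placebo 1) and macrophage -0.070 to 0.72 (ERbKO E2 3 or ERbKO placebo 2). For ERbKO minus WT they were striated muscle -0.76 to 0.28 (WT placebo 1). For ERaKO placebo they were striated muscle -1.23 to 0.46 (WT placebo 1). For ERbKO placebo they were cholesterol synthesis -0.29 to 0.12 (WT placebo 4) and fatty acid synthesis -0.49 to 0.18 (WT placebo 4).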

Other observations

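With the replicate number as a block, the probe sets that fell with E2 were shared between WT and ERaKO. This comparison was chosen after the results were seen. Of 148 that fell in WT and 321 that fell in ERaKO, 59 were the same, against 2.33 expected by chance (Fisher's exact test, p = 5.3e-68). With the brown adipocyte score added to the block, 3 fell and 14 rose in WT, and 0 fell and 0 rose in ERaKO, so both directions lost calls and the shared falls are not shown to be apart from fat cell content or to follow it. Of 31 probe sets that rose in ERbKO, 30 were among the 199 that rose in WT, against 0.30 expected (Fisher's exact test, p = 1.5e-60). The block fit made 7 to 17 false calls per contrast on simulated values, and Fisher's test takes probe sets as independent, which those of genes expressed together are not.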
